A study of Ipomoea batatas with 2 samples.

How the data were processed

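Small RNA was sequenced from leaves of sweet potato, cultivar Tainung 57. Per the labels, total RNA was extracted with Trizol, treated with DNase I and made into libraries with the standard Illumina protocol, and the leaves had been left unwounded or were wounded with tweezers and taken 0.5 h later. The labels put 1 library in each group, 2 libraries in all. The authors deposited for each library a list of distinct sequences with whole-number read counts, and the counts are not normalized. The base caller, the adapter trimming and any filter are not given in the sources used here. In the deposited counts the tags were 1 to 51 nt long, and 0.832% of the unwounded and 0.574% of the wounded reads held an undetermined base. The start of the usual small RNA adapter, TGGAATTCTC, was found in 0.0733% of the unwounded and 0.0884% of the wounded reads. Pieces too short to be miRNAs or siRNAs count in the totals, which lowers the share of the other classes where such pieces are more frequent.

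From the counts, reads per 1000000 reads of the library (RPM) were computed for each tag and family. The totals were 16298335 reads in the unwounded and 15661977 in the wounded library. At these depths 0 reads allow up to 0.184 and 0.192 RPM, taken as 3 counts. Reads were counted without molecular identifiers, so that all intervals and limits cover counting error only. Ratios of wounded to unwounded have the exact conditional binomial (Clopper-Pearson) 95% interval scaled by the totals, and shares have the Clopper-Pearson interval. The interval of the median over families comes from 1000 Poisson draws. No test was made between groups of 1 library, and a rule of size took its place: a ratio of at least 2-fold either way, an interval excluding 1 and at least 10 RPM in the higher library.

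A tag of 20 to 22 nt was given to a miRNA family when, aligned from the first base without gaps, it had at most 2 mismatches to a listed mature sequence, with the fewest mismatches deciding and ties left out. The list held 56 sequences of 35 conserved families and, as controls, 5 families known only from Arabidopsis and its relatives and 5 animal miRNAs. The control families had 0 reads in both libraries. Families were taken into 7 groups by function, and each group's median log2 ratio was set against 10000 random lists of 20- to 22-nt tags outside the families. Each member was drawn from the 200 tags nearest to it in abundance. For the most abundant families these are the 200 most abundant tags, most of them far less abundant than the family. A family is also a sum of tags, while a list holds single tags. Pieces of structural RNA were exact substrings of 18 nt or longer of 5 nuclear tRNA and 2 rRNA sequences. The families and tags named were fixed by rule: miR828 and the copper and lignin families, the 10 families with the largest and the 10 with the smallest ratio among those at 10 RPM, the 5 most abundant families, and of single tags at 100 RPM the 10 largest and 10 smallest ratios with at most 3 sequences printed each way, beside 2 to 4 members of each group. These lists, rules and choices were fixed before the data were examined.

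After the tags had been seen, a longer list of 25 tRNAs was added, 7 nuclear, 17 plastid and 1 mitochondrial. It was written from knowledge of conserved plant tRNAs and the tags themselves, not from a sweet potato genome, so that a name gives the tRNA's identity and genome as known in other plants. Fragments of these tRNAs were exact prefixes of 14 nt or longer, and those ending from 2 nt before to 3 nt after the last base before the anticodon were counted as ending in the anticodon loop. No tag was placed on a genome, and gene coordinates were not used here. First bases, duplex partners with a 2-nt 3' overhang, tags in common and length variants of the main tag of each family were counted from the tag lists alone.

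Other scalings were DESeq2 1.42.0 size factors and edgeR 4.0.16 TMM factors over the 78264 tags with 10 or more counts in both libraries, the reads of conserved families, and reads of 18 to 28 nt. They add 0.06, 0.07, 0.37 and 0.16 to every log2 ratio. Other matching rules, floors, lengths and thinned depth were tried as well, and their effect is given with the closing observations. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

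The size rule was tested on data simulated for this comparison over 4331 tags with the real means and totals. It recovered 100% of 50 tags at each of 2.5-fold and 4-fold, higher and lower, and took 0 of 4131 unchanged tags, of which 92.4% had an interval holding 1. The counts were drawn with Poisson error alone, and the changes were planted in the more abundant tags. The outcome therefore says nothing on how often the rule is passed through variation between libraries of the same condition. Planted tags with up to 2 mismatches to a listed sequence were all given to their own family (1320 of 1320 at each number of mismatches), and 1.21% of those with 3 were. None was given to another family.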

Results

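Small RNAs of sweet potato leaves (Ipomoea batatas, cultivar Tainung 57) were sequenced in 1 library from unwounded leaves and 1 library from leaves wounded with tweezers 0.5 h earlier. The comparison asks which small RNAs of the leaf differ early after mechanical wounding. Each library is a list of distinct sequences, called tags here, with the number of reads of each. The unwounded library held 16298335 reads in 4901931 tags and the wounded library 15661977 reads in 4451791 tags. Tags with 1 read made up 78.3% of the tags in the unwounded and 78.5% in the wounded library. Abundance is given in reads per 1000000 reads of the library (RPM), so that 10 RPM stands for 163 reads in the unwounded and 157 in the wounded library. A tag with 0 reads has an upper limit of 0.184 RPM in the unwounded and 0.192 RPM in the wounded library. With 1 library per condition no difference below has a replicate check, and every comparison is of these libraries, not of the conditions. Intervals are exact 95% intervals and cover counting error only. A family or tag is said to have risen or fallen when its ratio was at least 2-fold, the interval excluded 1 and the higher library had at least 10 RPM.

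Most conserved miRNA families at 10 RPM were lower in the wounded library by less than 2-fold, and 1 family, miR3627, fell. Its reads went from 143 RPM in the unwounded to 45.5 RPM in the wounded library, a ratio of 0.319 (0.293 to 0.347). No family rose. Of the 35 families listed, 21 reached 10 RPM, and their median log2 ratio of wounded to unwounded was -0.28 (-0.33 to -0.25). Most miR3627 reads were of the 22-nt tag TTGTCGCAGGAGAGAAGGCACT, at 131 and 42.1 RPM, which has 1 mismatch to the listed mature sequence, and no read matched that sequence exactly. Whether this tag is the sweet potato member of the family stays uncertain, since no precursor was searched for here.

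The most abundant family was miR165/miR166, known to act on the HD-ZIP III transcription factors that set leaf polarity, at 73037 RPM in the unwounded and 51395 RPM in the wounded library (ratio 0.704, 0.702 to 0.706). It made up 71.2% of the reads of conserved families in the unwounded and 65.0% in the wounded library. Next came miR398, known to act on copper/zinc superoxide dismutase, at 18440 and 17979 RPM (ratio 0.975, 0.970 to 0.980). miR396, a regulator of growth-regulating factors, stood at 2518 and 1870 RPM, with a ratio of 0.743 (0.732 to 0.754). The ratio of miR403, which acts on ARGONAUTE2 mRNA, was 0.840 (0.826 to 0.854) at 1901 and 1597 RPM. miR156/miR157, regulators of SPL transcription factors, had 2450 RPM in the unwounded and 2796 RPM in the wounded library, a ratio of 1.14 (1.13 to 1.16). It was the only one of the 21 families with a log2 ratio above 0 when scaled to all reads with up to 2 mismatches.

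The other 20 families at 10 RPM had log2 ratios below 0, and the interval lay below 1 for 18 of them and held 1 for miR393 and miR394. After miR3627 the lowest log2 ratios were those of miR162, which acts on DICER-LIKE1 mRNA (-0.52), miR165/miR166 (-0.51), miR169, which acts on NF-YA transcription factors (-0.47), miR396 (-0.43) and the TAS3 tasiARF siRNAs, which act on auxin response factors (-0.42). Reads of conserved families were 10.3% of the unwounded and 7.91% of the wounded library. Scaled to these reads, which sets the families against their own sum, every log2 ratio lies 0.37 higher, the median becomes 0.093, 15 of the 21 families lie above 0, and the 6 below 0 are miR3627, miR162, miR165/miR166, miR169, miR396 and TAS3 tasiARF. Scaled to reads of 18 to 28 nt every log2 ratio lies 0.16 higher. miR3627 fell under each of these scalings. With 0 mismatches allowed, miR398 (125 and 142 reads, log2 ratio 0.24), miR393 (121 and 139, 0.26), miR159 (109 and 116, 0.15) and TAS3 tasiARF (18 and 19, 0.14) lie above 0 and miR2111 (44 and 10) is at -2.08, each at less than 10 RPM. The main tag of each of these has 1 or 2 mismatches to the listed sequence, so this setting leaves out most of their reads, for miR398 all but 125 of 300535 in the unwounded library. The same holds for miR482/miR2118 (35 and 33 reads left). Values with 0 mismatches given for these families below rest on the few reads left and do not stand for the families.

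**Figure D1:**
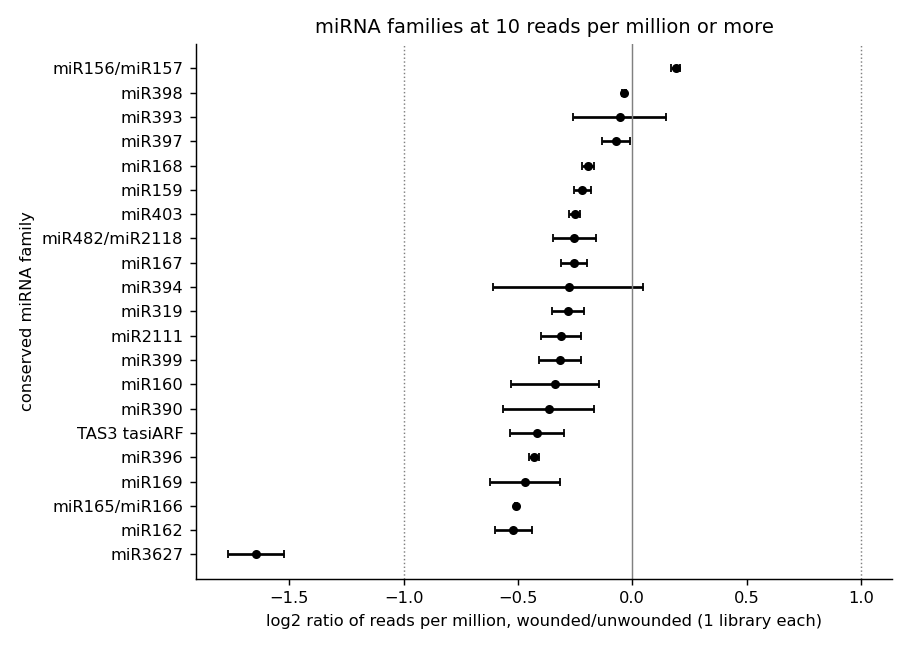
Log2 ratio of RPM (wounded over unwounded, 1 library each) for the 21 conserved miRNA families with at least 10 RPM. Points are ratios, bars are exact 95% counting intervals, and dotted lines mark 2-fold. miR3627 (-1.65) lies beyond the 2-fold line, and the other 20 families lie between -0.52 and 0.19; scaled to reads of conserved families all points move right by 0.37 and 15 lie above 0.

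Among the groups of families fixed beforehand, the copper and lignin group had the highest median log2 ratio (-0.05, percentile 75.1 among 10000 random lists of the tags nearest in abundance). Of its members, miR397, which acts on laccases, had 269 and 256 RPM (log2 ratio -0.07, and 0.098 with shifted starts), miR398 had a log2 ratio of -0.04 (0.24 with 0 mismatches), and miR408 had 6 and 4 reads, too few to compare. Both measured members lie above 0 when scaled to reads of conserved families, and the group median is 0.0085 with DESeq2 factors and 0.11 with 0 mismatches. The developmental transcription factor group, with miR156/miR157, miR165/miR166, miR169 and miR396 among its 6 measured members, had the lowest median under the matching rule used (-0.45, percentile 21.9). With 0 mismatches its median was -0.43 and that of the nutrient group, -0.71, was the lowest. This -0.71 is the value of miR395 alone, with 17 and 10 reads (ratio 0.612, 0.250 to 1.42), too few to rank the groups. In the MYB group miR828, a known trigger of phased siRNAs from MYB mRNAs, had 0 reads in both libraries, while miR159 had a log2 ratio of -0.22 (0.15 with 0 mismatches, -0.54 with starts shifted by up to 2 nt) and miR319 of -0.28. The other measured member, miR858, had 37 and 13 reads (ratio 0.366, 0.178 to 0.704), below the 10 RPM floor. The group median was -0.28 (percentile 50.6). The auxin group, 6 families with miR160 (-0.34), miR167 (-0.25) and miR390 (-0.37), had a median of -0.35 (percentile 35.8). The nutrient group, with the phosphate-starvation families miR399 (-0.32) and miR2111 (-0.31, and -2.08 with 0 mismatches), had a median of -0.38 (percentile 36.7). For the silencing machinery, miR162, miR168 (1544 and 1351 RPM, log2 ratio -0.19) and miR403 (-0.25), it was -0.25 (percentile 51.5). The group of disease resistance regulators and phased siRNA triggers had a median of -0.31 (percentile 43.9; -0.027 with 0 mismatches), with miR482/miR2118 at -0.25 (-0.72 with 3 mismatches) and miR3627 as the 1 member of any group that fell. The 7 percentiles lay between 21.9 and 75.1. Scaled to all reads 7 of the 7 medians were below 0, and 6 with DESeq2 factors.

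The single tags that rose were mostly under 18 nt or started as a tRNA. Of 4973 tags with at least 10 RPM in either library, 782 rose and 280 fell. Tags under 18 nt accounted for 520 of the rises and 22 of the falls, out of 1306 such tags. Of 396 tags that started as a tRNA of the list used here, 183 rose and 83 fell. For single tags such a start means that the first 14 nt match with at most 1 mismatch, so that variants count beside exact prefixes. The 154 tags of miRNA families included 0 that rose and 43 that fell, of which 38 belonged to miR165/miR166. These tags include length and mismatch variants of the same sequences, so they are not separate small RNAs. Sequencing errors among them were not told apart. The 71 tags of miR165/miR166 had a median log2 ratio of -1.03, against -0.51 for the family. Such an offset was not particular to it, as the 24 tags of miR398 had -0.59 against -0.04 and the 9 of miR403 -0.71 against -0.25. In miR168 the 4 tags lay the other way (0.11 against -0.19). Of the 24-nt tags, the usual size of siRNAs of RNA-directed DNA methylation, 10 of 1389 rose and 7 fell, while 12 of 342 tags of 22 nt rose and 54 fell.

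Among the 501 tags with at least 100 RPM the largest ratio was that of the 9-nt tag AGGGCTATA, from 11.2 to 613 RPM (54.6-fold, 47.2 to 63.6). The next were the 6-nt tag CCGACC, from 2.76 to 139 RPM (50.3-fold, 37.5 to 69.2), and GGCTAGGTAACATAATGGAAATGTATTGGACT, the 5' part of a mitochondrial tRNA-Cys(GCA), from 2.95 to 139 RPM (47.2-fold, 35.4 to 64.2). Of the 10 largest ratios, 7 belonged to tags that start as a listed tRNA. The largest fall was that of the 15-nt tag AATCATGTGGGCTCT, from 110 to 13.8 RPM (7.96-fold lower, 6.91 to 9.21). The 22-nt tag CCTAAGATGAGCTCAACGAGAA fell from 109 to 30.3 RPM (3.58-fold lower, 3.24 to 3.97). Of the 10 smallest ratios, 4 were of tags that start as plastid tRNA-Asp(GTC), and the miR3627 tag was another. These 4 are forms of the same fragment, 33 or 34 nt long, and include variants that are not exact prefixes. AGGGCTATA and CCGACC are too short to be assigned to a gene.

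Fragments from the 5' end of nuclear tRNAs that stop in the anticodon loop rose for 7 of 7 nuclear tRNAs of the longer list. That list was written in part from these tags. Summed, they went from 5582 to 35139 RPM (6.29-fold, 6.25 to 6.34). Most of this sum was tRNA-Glu(TTC), with 5243 RPM in the unwounded and 31757 RPM in the wounded library (6.06-fold). The ratios of the 7 tRNAs ran from 2.02 (1.87 to 2.19) for tRNA-Gln(TTG) to 27.4 (25.6 to 29.3) for tRNA-Glu(CTC). The fragment that stops just before the anticodon rose more, from 1101 to 19628 RPM over the 6 nuclear tRNAs where it reached 10 RPM (17.8-fold, 17.6 to 18.1). tRNA-Glu(TTC) alone supplied 928 RPM of it in the unwounded and 16966 RPM in the wounded library (18.3-fold, 17.99 to 18.59). The same fragment rose 34.6-fold (31.9 to 37.6) for tRNA-Glu(CTC), 21.2-fold (19.5 to 23.2) for tRNA-Asp(GTC), 18.7-fold (16.5 to 21.2) for tRNA-Gly(TCC), 4.76-fold (4.26 to 5.32) for tRNA-Gly(GCC) and 3.69-fold (3.44 to 3.96) for tRNA-His(GTG). Of all 5' fragments of tRNA-Glu(TTC), the 16-nt piece, which ends in the D arm, had 7461 and 9773 RPM (1.31-fold, 1.30 to 1.32).

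**Figure D2:**
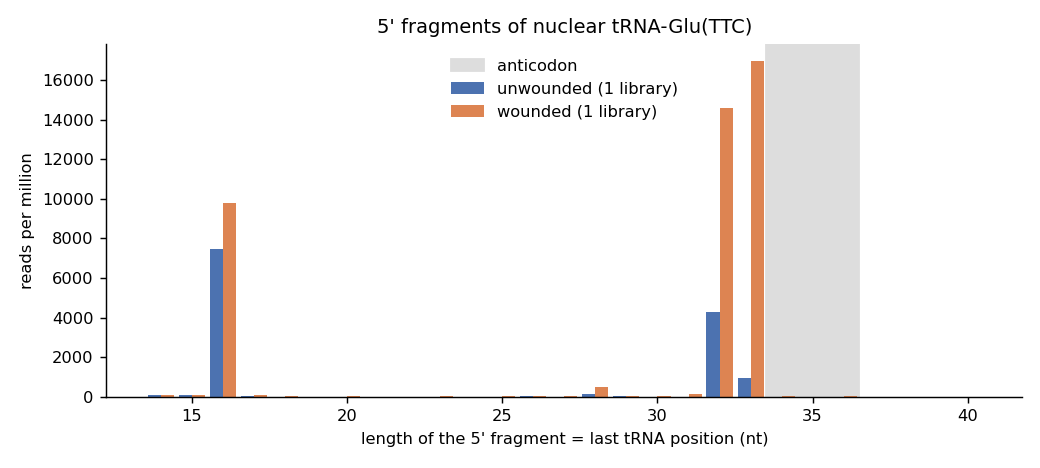
Abundance in RPM of 5' fragments of nuclear tRNA-Glu(TTC) by the position at which they end, in the unwounded and the wounded library (1 library each). Fragments of 33 nt, ending just before the anticodon (grey), had 928 RPM in the unwounded and 16966 RPM in the wounded library, and those of 32 nt 4290 and 14598 RPM, while the 16-nt piece had 7461 and 9773 RPM.

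Plastid tRNAs did not move together. Of 16 plastid tRNAs whose anticodon-loop fragments reached 10 RPM, 8 rose, 2 fell and 6 did neither, and their sum was 19697 RPM in the unwounded and 11823 RPM in the wounded library (ratio 0.600, 0.597 to 0.604). The sum was led by tRNA-Asp(GTC), whose fragments fell from 16205 to 6586 RPM (ratio 0.406, 0.403 to 0.409). tRNA-His(GTG) fell as well (ratio 0.419, 0.370 to 0.473), while tRNA-Phe(GAA) went from 1350 to 876 RPM (ratio 0.649) without passing the rule. Rises were seen for tRNA-Gly(TCC) (28.1-fold, 25.7 to 30.8), tRNA-Glu(TTC) (21.3-fold, 17.4 to 26.4), tRNA-Gln(TTG) (8.14-fold, 7.58 to 8.75) and tRNA-Lys(TTT) (6.79-fold, 6.19 to 7.46). The mitochondrial tRNA-Cys(GCA) rose 17.1-fold (14.8 to 19.7). The count of 16 rises over the 24 tRNAs was the same under all 5 scalings, and the 2 falls passed the rule under 4 of them but not when scaled to reads of conserved families. Each of the other scalings raises every log2 ratio, so none of them could have removed a rise.

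**Figure D3:**
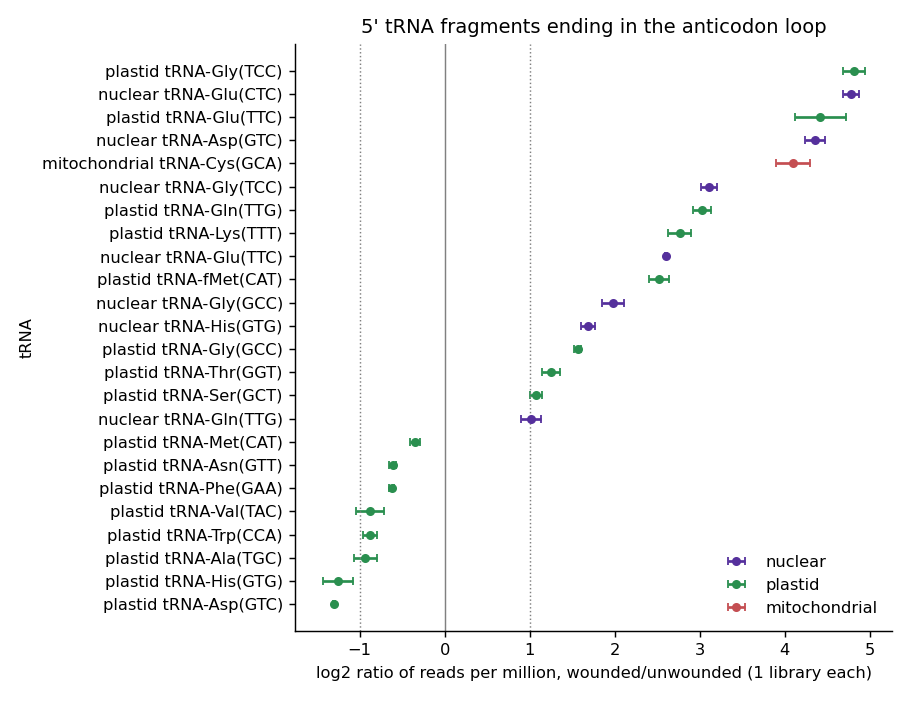
Log2 ratio of RPM (wounded over unwounded, 1 library each) of 5' fragments that end in the anticodon loop, for 24 tRNAs with at least 10 RPM, coloured by genome. Points are ratios, bars are exact 95% counting intervals, and dotted lines mark 2-fold. All 7 nuclear tRNAs and the mitochondrial tRNA lie above 0, and the 16 plastid tRNAs lie between -1.30 and 4.81; the signs are the same under the other scalings except for plastid tRNA-Met(CAT), at -0.35, which is above 0 when scaled to reads of conserved families.

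Shorter 5' fragments of 14 to 24 nt rose for 10 of 21 tRNAs and fell for 0. The widest difference was for plastid tRNA-Arg(ACG), from 36.2 to 1176 RPM (32.5-fold, 29.9 to 35.3), nearly all of it a 19-nt piece. Plastid tRNA-Gln(TTG) rose 7.95-fold (7.64 to 8.27), plastid tRNA-fMet(CAT) 3.88-fold (3.70 to 4.07) and plastid tRNA-Asp(GTC) 2.71-fold (2.62 to 2.81), the last in the opposite direction to its anticodon-loop fragments. The tRNA list behind these counts was drawn up after the tags had been seen. In the list fixed before, pieces of 18 nt or longer from 5 nuclear tRNAs summed to 322 and 761 RPM (2.36-fold, 2.29 to 2.44). Of these, Gly-GCC (2.09-fold), Asp-GTC (6.48-fold) and iMet-CAT (2.98-fold) rose, while Glu-CTC (52.03 and 83.5 RPM, 1.61-fold, 1.47 to 1.75) and His-GTG (4.23 and 3.13 RPM, ratio 0.739, 0.502 to 1.08) did not. In the longer list, 5' fragments of nuclear tRNAs of the same names had 475 and 2498 RPM for Glu(CTC) and 135 and 339 RPM for His(GTG). Exact pieces of the sequences fixed before thus missed many reads of these tRNAs, and their ratios do not stand for all of the fragments. In the same list pieces of 5.8S and 5S rRNA had 5774 and 6126 RPM (ratio 1.06, 1.05 to 1.07), with 5.8S at 1.09 (1.08 to 1.10) and 5S at 0.862 (0.839 to 0.886). Together the tRNA and rRNA pieces were 0.610% of the reads in the unwounded and 0.689% in the wounded library.

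Reads of 20 to 24 nt, the size of miRNAs and siRNAs, took a smaller share of the wounded library and very short reads a larger one. Together those of 20 to 24 nt were 74.8% of the unwounded and 65.9% of the wounded library. Those of 24 nt were 38.1% and 33.9%, those of 21 nt 20.8% and 16.9%, and those of 22 nt 6.53% and 5.51%, while those of 20 nt (2.74% and 2.86%) and 23 nt (6.57% and 6.74%) were slightly higher in the wounded library. Reads of 1 to 15 nt were 6.46% and 12.04%, and reads of 32 to 33 nt, lengths found among the anticodon-loop fragments, 3.08% and 5.12%. The ratio of 24-nt to 21-nt reads was 1.83 (1.832 to 1.837) in the unwounded and 2.00 (2.001 to 2.007) in the wounded library. Counted over distinct tags it was 8.35 and 8.14, with the order of the libraries turned.

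**Figure D4:**
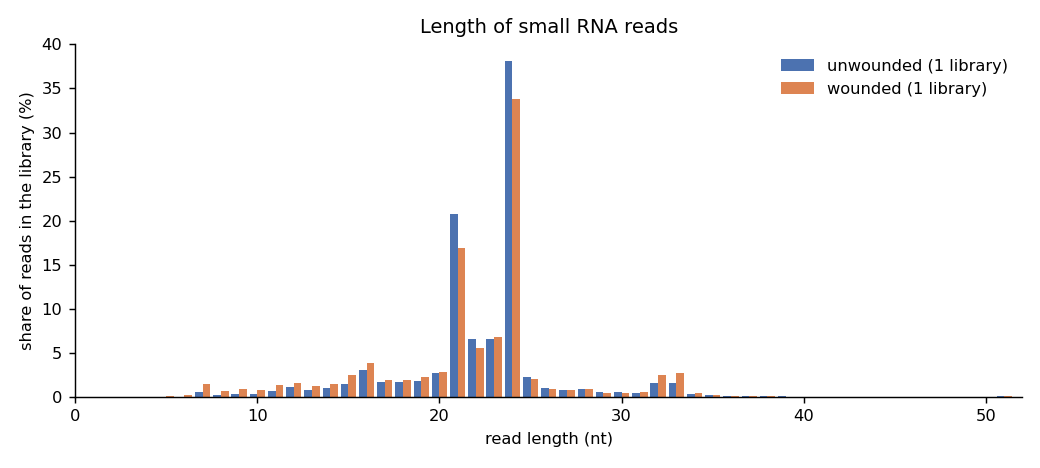
Share of reads (%) by read length (nt) in the unwounded and the wounded library (1 library each). The 24-nt peak stands at 38.1% and 33.9% and the 21-nt peak at 20.8% and 16.9%, and reads under 18 nt and of 32 to 33 nt take larger shares of the wounded library.

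The first base of a small RNA goes with the ARGONAUTE protein that binds it. T, read for U, was the first base of 80.4% of 21-nt reads in the unwounded and 77.3% in the wounded library, and A of 74.8% and 73.0% of 24-nt reads. In 22-nt reads G as the first base went from 8.92% to 12.4%. The share of 21-nt tags with a perfect partner at a 2-nt 3' overhang, the form in which Dicer releases duplexes, was 7.20% (7.11 to 7.29) in the unwounded and 6.91% (6.82 to 7.002) in the wounded library, but by reads the order turned, with 9.25% (9.21 to 9.28) and 9.90% (9.87 to 9.94). For 22-nt tags it was 6.19% and 4.98%, and for 24-nt tags 4.22% and 4.67%. Overhangs of 3 nt gave higher shares of tags (7.65% and 7.16% for 21-nt tags), and by reads 15.76% and 8.70%, so that the shares of tags do not separate Dicer duplexes from other overlaps. The libraries shared 1152032 tags, which held 73.6% of the unwounded and 76.1% of the wounded reads.

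Length variants of miRNAs were counted from the main tag of each family. The shares below are of reads that are the main tag or a 3'-shortened or 3'-lengthened form of it, not of all reads of the family. For miR396 such reads numbered 20450 in the unwounded library, beside 41032 reads of the family. Over the 21 families at 10 RPM, the median share of such reads equal to the main tag was 96.2% in the unwounded and 96.1% in the wounded library. The median share of 3'-shortened reads was 1.64% and 2.19%, higher in the wounded library for 16 of the 21 families and with intervals apart for 6 of them, all higher in the wounded library, miR167 among them (24.2%, 22.7 to 25.7, and 29.1%, 27.4 to 30.8). An added 3' T had a median share of 0.240% and 0.191%, and its intervals lay apart for miR156/miR157 alone (4.78%, 4.54 to 5.02, and 3.28%, 3.10 to 3.47).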

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

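The scalings, matching rules and floors below were chosen before the data were examined, except the longer tRNA list, the scalings of its counts and the rule of 3 mismatches, which were added after. No paired analysis was possible because each group has 1 library, and leaving out a library is not possible for the same reason. The fall of miR3627 passed the size rule under all scalings and matching rules except 0 mismatches, where it had no reads and the count of families that fell was 0. With a floor of 1 RPM the count was 2, miR858 being the other, with 37 and 13 reads. No alternative gave a family that rose. With 0 mismatches the median log2 ratio was -0.20, over the 20 families other than miR3627, some of them below 10 RPM at that setting. The median of the 21 families was -0.22 with DESeq2 factors, -0.21 with TMM factors, -0.12 scaled to 18- to 28-nt reads and 0.093 scaled to reads of conserved families. This last scaling divides the families by their own sum and so centres them, and the sign it gives says nothing on the direction against the other RNA. The count of group medians below 0 was 2 with that last scaling. Tags that rose numbered 6438 with a floor of 1 RPM, 121 with a floor of 100 RPM and 58 when only 20- to 24-nt tags were counted, and tags that fell 5892, 31 and 146, because these settings change how many tags enter. The falls of anticodon-loop fragments numbered 0 scaled to reads of conserved families, where plastid tRNA-Asp(GTC) and tRNA-His(GTG) stayed short of 2-fold.

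The ratio of 24-nt to 21-nt reads in the unwounded and wounded library was 8.35 and 8.14 over distinct tags, 1.83 and 1.99 without the listed tRNA and rRNA pieces, 5.26 and 5.66 without the 100 most abundant tags, and 1.30 and 1.45 without tags of 1 read. T as the first base of 21-nt reads was 38.8% and 34.7% over distinct tags and 62.1% and 58.1% without conserved families, and A of 24-nt reads 68.9% and 67.1% over distinct tags. Structural pieces were 1.43% and 1.68% of reads with 1 mismatch, 0.714% and 0.867% from 15 nt on, and 3.43% and 5.85% with the longer tRNA list. Duplex partners of 21-nt tags were 10.1% and 9.86% without tags of 1 read. Those of 24-nt tags were 3.05% and 3.26%, and 4.15% in the unwounded library thinned to the same total. Shared tags numbered 464133 without tags of 1 read. The cause of these shifts was not tested beyond the tags each setting leaves out. Of 235 alternatives for single families and groups, 146 stayed within the counting interval, 89 moved and 0 turned a family that passed the rule. Only miR3627 passed it, so this 0 covers 1 family, and changes of sign in other families or groups were not counted as turned. miR482/miR2118 had a log2 ratio of -0.72 with 3 mismatches and -0.74 with starts shifted by up to 2 nt, against -0.25, and miR159 0.15 with 0 mismatches and -0.54 with shifted starts, against -0.22. With 0 mismatches miR2111 had -2.08 against -0.31, TAS3 tasiARF 0.14 against -0.42, miR398 0.24 against -0.04 and miR393 0.26 against -0.06. For these 4 and for miR159, that setting leaves out the main tag and most reads of the family. miR397 had 0.098 with shifted starts against -0.07.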

Other observations

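The tests with rRNA pieces, with 30- to 35-nt reads outside the tRNA list, with random lists over all families, with 22-nt tags and with the number of libraries were chosen after the result was seen, while scaling to 18- to 28-nt reads and shifted starts had been planned, though what they would show for each explanation was written after, and the tags named here were picked after their values were seen. Some of the most abundant tags lay outside the family rule. AGTTACTAATTCATGAGCTGGC, 22 nt long, had 12227 RPM in the unwounded and 12400 RPM in the wounded library, and TCTCGGACCAGGCTTCATTCC, which overlaps miR165/miR166 with a shifted start, had 33316 and 26994 RPM (ratio 0.810, 0.807 to 0.814). TTTCCTATGCCTCCCATTCCTA, a 22-nt tag that joins miR482/miR2118 when 3 mismatches are allowed, had 2559 and 1497 RPM (ratio 0.585, 0.576 to 0.595). Among 20- to 24-nt tags with no match, CGGCGGACTGCTCGAGCTGC rose from 56.6 to 1131 RPM (19.97-fold, 18.7 to 21.4) and ATACGAAGTATAGAATCGAAGCG from 2.15 to 72.7 RPM (33.8-fold, 24.2 to 48.8), while ATGAGATGAAACCTGAAAACAACC fell from 12.9 to 0.511 RPM (25.2-fold lower, 12.6 to 59.2).

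Reads starting in the anticodon loop were counted for the 6 tRNAs whose listed sequence reaches far enough past it, and they numbered at most 34 per tRNA and library. Those of nuclear tRNA-Glu(TTC) numbered 10 in the unwounded and 7 in the wounded library, beside 85452 and 497375 reads of its 5' fragments ending there. For nuclear tRNA-Gly(GCC) they numbered 34 and 34, beside 619 and 2346. Pieces of 15 to 17 nt of 5.8S and 5S rRNA had 634 and 770 RPM (ratio 1.21, 1.18 to 1.25). Tags ending in GACCGGTAGACTTGAAC, a sequence that was not assigned to a gene here, had 35501 and 28859 RPM (ratio 0.813, 0.810 to 0.816).

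The rise of 5' fragments of nuclear tRNAs ending in the anticodon loop (6.29-fold, 7 of 7 tRNAs) was set against technical explanations. The list of these tRNAs was written in part from the tags, after they had been seen. Better recovery of 30- to 35-nt inserts would raise other reads of that length, but those outside the tRNA list had a log2 ratio of -0.25. Breakdown of all RNA in the wounded sample stays open: rRNA pieces of 28 to 36 nt had a log2 ratio of -0.20, but those of 15 to 17 nt and 18 to 27 nt were higher (ratios 1.21 and 1.11), reads of 1 to 15 nt went from 6.46% to 12.04%, and 3'-shortened miRNA reads were higher in 16 of 21 families. Wounding and a library difference other than wounding cannot be told apart, since there is 1 library per group.

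The lower median of the conserved miRNA families (-0.28) was set against the make-up of the libraries. A larger share of reads under 18 nt or over 28 nt can account for part of it. Scaled to 18- to 28-nt reads, which adds 0.16, the median was -0.12 (-0.17 to -0.09), an interval that excludes 0. Whether it accounts for the whole cannot be decided. The interval covers counting error only. With 0 mismatches the median was -0.20 before this scaling, but over the 20 families other than miR3627. Some of these lie below 10 RPM at that setting, so -0.20 is not the same measure as -0.28. A lower share of 20- to 22-nt RNA of every kind remains a possible explanation: the median of -0.28 lay at percentile 45.1 of 10000 random lists of such tags outside the families, matched on abundance. Of single family tags 43 of 154 fell, against 84 of 969 tags of 20 to 22 nt outside the families. This difference rests on miR165/miR166, as 5 of the 83 tags of the other families fell. The family tags include variants of the same sequences, so they are not separate small RNAs, and sequencing errors were not told apart. Reads with an undetermined base were 0.832% of the unwounded and 0.574% of the wounded library. Whether error rates differ between the libraries was not tested, so the counts of single tags do not decide the question. With 1 library per group, wounding and a library difference other than wounding cannot be told apart here either.

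The fall of miR3627 (log2 ratio -1.65, -1.77 to -1.53) was set against other 22-nt tags. Reads moved to other starts of the same RNA do not account for it, as the log2 ratio was -1.65 with starts shifted by up to 2 nt also counted. The 22-nt tags at 10 RPM outside the families had a median log2 ratio of -0.47. An equal fall of all 22-nt RNA by that much would account for part of -1.65 at most. A fall of 22-nt RNA that varies between tags stays open: 9 of 322 of them (2.80%) were as low as miR3627. A list of 4 such tags, the number of families with a 22-nt main tag, would hold one as low with a chance of 0.107. These tags were not matched to miR3627 on abundance. With 1 library per group, a library difference other than wounding cannot be told apart from an early response of miR3627 either.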
